A study of Rattus norvegicus with 6 samples.

How the data were processed

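The data were bulk RNA-seq profiles of total lung from Sprague-Dawley rats, 3 wild-type (WT) and 3 Ahr-knockout (Ahr-KO) samples. All were labelled with Sugen-Hypoxia treatment and day 56. Per the labels' protocols, RNA was extracted with Trizol and a column kit with DNase, and libraries were made with a standard Illumina procedure. Per the submitters' processing notes, FastQC was used and the genome build was rn6. The aligner, the counter, the gene annotation and the strandedness are not given in the sources used here.

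The authors deposited 1 table with 1 value per gene symbol and library, used here as a normalised signal that is never negative. The values behaved as estimated read counts divided by 1 factor per library: 97.5% to 98.0% of the values above 0 in a library lay within 0.05 of a whole multiple of a recurring step. Because the rest were fractions, the deposited values were not treated as counts, and the test planned for counts was replaced by the one planned for normalised values. The total value divided by the step estimated 12.9 to 21.9 M reads per WT library and 14.2 to 23.6 M per Ahr-KO library. At this depth 1 read corresponded to a value of 0.81 to 1.40, so genes near that level carry large counting error. The table held 19828 entries. Of these, 25 had symbols that look like dates, 2 symbols stood on more than 1 line and 229 entries named several genes together. They were kept as deposited, and genes with close relatives are named as uncertain where reads could have been shared. There were 0 columns of values left unused.

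The table's columns showed the genotype, the treatment and the day, with a further field NO that the sample titles do not explain. They numbered the libraries from 0 to 2, whereas the sample titles count from 1. Columns were therefore assigned to groups and not to single samples, and the numbers serve only as names. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. No library pair differed by as little as sampling noise (the lowest chi-square per gene was 15.4 over all pairs). This does not show that the samples came from separate animals, and n counts 3 libraries in each group.

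The 1 comparison was Ahr-KO against WT. Values were transformed to log2(value + 1), genes with a value of at least 1 in at least 3 libraries were kept (15386 genes), and limma 3.58.1 (in R 4.3.3) was fitted with genotype as the single term and a mean-variance trend (limma-trend, not robust). P-values are 2-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05 and no fold minimum. An exact permutation test of 3 against 3 samples cannot give a 2-sided p below 0.1, so single genes were tested only within this model. Fold values are the log2(value + 1) differences taken back to the linear scale, so for genes with low or uneven values they differ from the ratio of the group means.

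Before the data were examined, 35 gene lists (566 symbols, 542 found in the table) were written down for pathways, cell types and neighbouring tissues. Each list with at least 4 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with a correlation estimated per list, which called 0 of the 35 lists, and fry, which tests whether members move on balance one way without comparing them with other genes and called 13, of which 11 were also called by camera. Fixed at the same time were the test, the alternatives and the rule for named genes. The rule took Ahr, Arnt and the measured AHR targets; the 12 genes with the largest change in each direction, past the threshold, with a mean of at least 1 and with all 3 values of one group on one side of the other; up to 4 members with the lowest p from each list that was called or had at least 2 members past the threshold; and Y-linked genes as a check of the libraries. Xist and Uty are not analysed here. The rule gave 137 genes, 113 of them past the threshold, and not all of them are reported here by name. Further genes are named as chosen after their values were seen.

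The alternatives were quantile normalisation, limma without the trend, robust limma, no filter, a stricter filter, a pseudocount of 0.1, the library number as a block, each library left out in turn, an adjusted p under 0.10, a fold of at least 2, and the estimated correlation and fry for lists. Chosen after seeing the data were limma-voom on values divided by the step, values rescaled to equal library totals, and the fit without both libraries numbered 2. The code was tested on simulated data for this comparison, with 200 of 15250 genes changed: it recovered 91% of the genes changed 2-fold and 100% of those changed 4-fold, 4.02% of its calls were false, 0 genes were called when none was changed, and 0 of 30 random lists were called. The simulated genes were drawn independently of each other, so the simulation does not test lists whose members are correlated. In the real data the estimated correlation was as high as 0.76, for the cardiac muscle list. A gene table of the rat assembly GRCr8 was used only for the order of genes beside Ahr. It matched 17308 of the table's symbols and 14419 of the 15386 tested, and no coordinates are given because the builds differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.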

Results

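The series compared total lung tissue from Sprague-Dawley rats of 2 genotypes, wild type (WT) and Ahr knockout (Ahr-KO). All samples were labelled with the Sugen-Hypoxia (SuHx) treatment and day 56. Ahr encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor. Sugen is an inhibitor of VEGF receptors, and given together with low oxygen it is a rat model of pulmonary arterial hypertension, the disease named in the series title. Bulk RNA-seq gave 1 library per sample, with 3 libraries in each group, and each value was a normalised, estimated read count per gene symbol. The libraries are numbered 0, 1 and 2 within a group, as in the table. The normalised values summed to 17.8 to 18.0 M (mega) in the WT libraries and to 18.9 to 19.3 M in the Ahr-KO libraries. The smallest step between values put the depth behind them at about 17.8, 21.9 and 12.9 M reads in WT libraries 0, 1 and 2. The estimates for Ahr-KO libraries 0, 1 and 2 were 23.6, 22.9 and 14.2 M, so the library numbered 2 was the shallowest of each group. All samples came from SuHx rats, so the comparison asked how the Ahr genotype was related to the lung transcriptome under this treatment. Values below are means ± SD over n = 3 libraries. Log2 fold changes are Ahr-KO against WT on the log2(value + 1) scale, ± SE, which understates the change of genes with low values. Folds are the same differences on the linear scale and are not ratios of the group means.

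Ahr itself was read at similar levels in both groups, while several of its best known target genes were close to silent in the libraries labelled Ahr-KO. Ahr stood at 2940.0, 2860.4 and 3395 in WT libraries 0, 1 and 2 and at 2399, 3923 and 3575 in the Ahr-KO libraries, a log2 fold change of 0.08 ± 0.18 with a 95% interval of -0.34 to 0.49 (adjusted p = 0.81). Cyp1a1, a cytochrome P450 that oxidises aromatic hydrocarbons, fell from 29430.5 ± 7376 to 4.22 ± 5.42, a log2 change of -12.94 ± 0.62 (adjusted p = 0.00024). Ahrr, the repressor that AHR induces against itself, fell from 1824 ± 475 to 5.09 ± 0.93 (log2 -8.21 ± 0.24, adjusted p = 9.4e-06). The related P450 gene Cyp1b1 fell from 3782 ± 1951 to 50.4 ± 22.1 (log2 -6.18 ± 0.39, adjusted p = 0.00051). Nqo1, a quinone reductase, was 5.04-fold lower in the Ahr-KO libraries (adjusted p = 0.0036).

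The position and kind of the Ahr edit are not given in the sources used here, and a gene-level value that includes exons outside an edit does not check the genotype labels. The Ahr fold change was slightly negative, at -0.01, after quantile normalisation and with equal library totals, and -0.06 without Ahr-KO library 1, each far from the threshold. Among the 12 tested members of the AHR target list, 8 fell, 1 rose and 3 did not pass the test. When adjusted over the list alone, 9 fell and 1 rose. The other members that fell were Tiparp, an ADP-ribosyltransferase that restrains AHR (2.46-fold, adjusted p = 0.024), the aldehyde dehydrogenase gene Aldh3a1 (2.31-fold, adjusted p = 0.029), the P450 gene Cyp2s1 (1.6-fold, adjusted p = 0.02) and Scin, which encodes the actin-severing protein scinderin (2.86-fold, adjusted p = 0.028). The member that rose was Fmo1, a flavin monooxygenase, from 2766 ± 819 to 6519.7 ± 218 (2.43-fold, adjusted p = 0.011). Lrat (log2 -0.94, adjusted p = 0.078), Xdh (log2 0.59, adjusted p = 0.18) and Nedd9 (log2 0.11, adjusted p = 0.82) did not pass. Arnt, the dimerisation partner of AHR, did not pass either (856 ± 156 against 951 ± 86.2, adjusted p = 0.51). Cyp1a2 was below the filter, at 1.40 in WT library 2 and listed at 0 in the other 5 libraries. The list was called lower by the set test (camera adjusted p = 5.5e-06, median log2 -1.25; adjusted p = 0.21 with an estimated correlation). Calls of Cyp1a1, Ahrr, Cyp1b1 and Nqo1 held in each fit that left out 1 library, with Cyp1a1 at a log2 of -13.76 without Ahr-KO library 0. Fmo1 lost its call without Ahr-KO library 2 (adjusted p = 0.053) and Cyp2s1 without WT library 0 or Ahr-KO library 2 (highest adjusted p = 0.07). Tiparp lost its call without WT library 0 or Ahr-KO libraries 1 or 2 (highest adjusted p = 0.10) and Scin without WT library 1 or Ahr-KO libraries 1 or 2 (highest adjusted p = 0.10). Aldh3a1 lost it without WT library 1 or any 1 of the Ahr-KO libraries (highest adjusted p = 0.11).

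**Figure D1:**
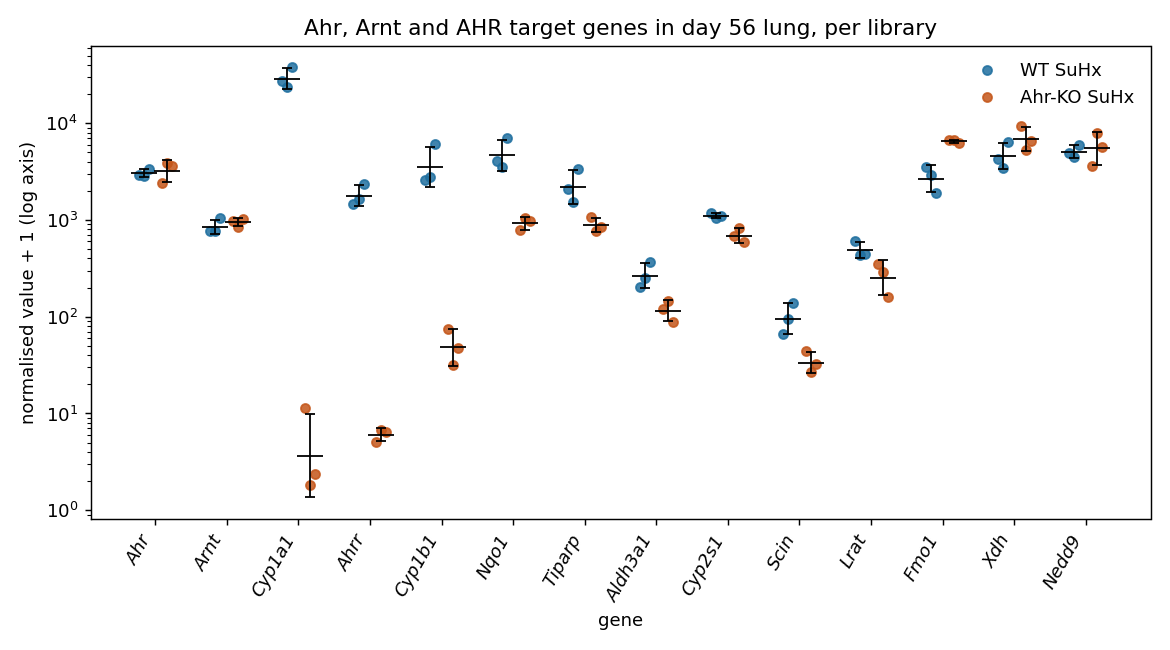
Normalised value + 1 on a log axis for Ahr, Arnt and the 12 tested AHR target genes, 1 point per library (blue WT SuHx, orange Ahr-KO SuHx), with the mean and SD of the log2 values as bars. Ahr lies between 2399 and 3923 in all 6 libraries, whereas Cyp1a1 lies at 23512 or more in the WT libraries and at 10.5 or less in the Ahr-KO libraries.

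Across the transcriptome, 1655 of 15386 tested genes (10.8%) differed between genotypes, with 692 higher and 963 lower in Ahr-KO (limma-trend, Benjamini-Hochberg adjusted p under 0.05). The larger changes were mostly decreases, since 541 of the genes that fell and 135 of the genes that rose changed at least 2-fold. The 3 values of one group all lay above those of the other for 5285 genes (34.3% of those tested, where chance gives 10%). The first principal component, with 54.8% of the variance, separated the genotypes. With the values rescaled to equal library totals, 448 genes were higher and 1314 lower, so the balance of rises against falls depended on the scaling. Quantile normalisation ended the calls of 13 of the named genes, Scin, Gpx2, Ccl20, Sdc1, Pou2af1, Ms4a2, Cpa3, Pecam1, Tppp3, Id3, Bmpr2, Vipr1 and Ace. Among genes named after their values were seen, it also ended those of Slc7a11 (adjusted p = 0.063) and Dnali1 (0.052). Limma-voom ended the call of Egr1 (0.062), and the fit with no filter that of Plvap (0.057). Limma without the trend ended those of Plvap (0.099), Dnali1 (0.090), Foxj1 (0.076), Dnah7 (0.070) and Arpc1b (0.065). It also ended those of Egr1 (0.063), Lrrn3 (0.063), Dnai2 (0.061), Fmo2 (0.057) and Dnah6 (0.054). The library number as a block ended those of Plvap (0.084), Dnali1 (0.068), Dnah7 (0.065) and Slc7a11 (0.059). With the block, Arpc1b (0.056), Dnai2 (0.051) and Fmo4 (0.051) were lost too. Of 35 gene lists, 19 were called by camera with a preset correlation of 0.01, 15 lower and 4 higher, and 0 with an estimated correlation (lowest adjusted p = 0.21, and 8 lists at an unadjusted p under 0.05). Of the 19, fry did not call the macrophage (adjusted p = 0.12), complement (0.063), capillary (0.09), pan-endothelial (0.14), smooth muscle (0.46), airway (0.072), immediate early (0.052) and red blood cell lists (0.18). It called hypoxia targets (0.034) and skeletal muscle genes (0.0072), which camera did not. When the libraries were split 3 and 3 so that the genotypes mixed, camera with the preset correlation still called 3 to 19 lists. The list calls by camera below therefore do not by themselves show a genotype difference. The number of changed genes was 407 without Ahr-KO library 2, 529 without Ahr-KO library 1, 705 without WT library 0 and 871 without WT library 1. It was 1461 without Ahr-KO library 0 and 1834 without WT library 2. Without WT library 2, 930 genes were higher and 904 lower, so the balance also depended on that library.

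The largest rises were in genes of varied function. Mlc1, a membrane protein best known from astrocytes, rose from 9.58 ± 9.49 to 408 ± 194 (log2 5.51 ± 0.61, adjusted p = 0.0043). Lyc2, a lysozyme gene, rose from 153 ± 30.1 to 1430.2 ± 214 (log2 3.22 ± 0.18, adjusted p = 0.00051), although it has a close relative in Lyz2 and reads shared between them leave its level uncertain. Kcnj6, an inwardly rectifying potassium channel gene, rose 10.35-fold and Tmem169 7.06-fold (adjusted p = 0.0054 and 0.0054). Cbs, the cystathionine beta-synthase of the transsulfuration pathway, rose 6.95-fold (adjusted p = 0.0079). The neuropeptide gene Gal rose 9.52-fold, the lysine catabolism gene Aass 6.64-fold and the water channel gene Aqp8 17.94-fold (adjusted p = 0.016, 0.012 and 0.018). The nicotinic receptor gene Chrna4 rose 6.95-fold, the synaptic vesicle gene Sv2c 15.25-fold and Hapln2, a hyaluronan link protein gene, 6.58-fold (adjusted p = 0.016, 0.03 and 0.041). Cacng3, a calcium channel and AMPA receptor subunit gene, was listed at 0 in the 3 WT libraries and at 8.06, 4.13 and 8.18 in the Ahr-KO libraries (adjusted p = 0.013). It entered only 3 of the fits that left out 1 library and passed in each. The rises of Gal and Aass were lost without Ahr-KO library 2 (adjusted p = 0.077 and 0.058) and that of Aqp8 without WT library 0 or Ahr-KO library 2 (highest adjusted p = 0.053). Chrna4 lost its call without WT library 0 or Ahr-KO libraries 1 or 2 (0.075) and Hapln2 without WT library 1 or any 1 of the Ahr-KO libraries (0.14). Sv2c lost it without any 1 library other than WT library 2 (0.093). Leaving out 1 library moved the size of 5 of these rises by over 1.5 times, Mlc1 to a log2 of 6.20 without WT library 1, Sv2c to 5.0 and Hapln2 to 2.03 without WT library 2, Aqp8 to 3.31 without Ahr-KO library 0 and Gal to 3.88 without Ahr-KO library 1.

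Among the genes with the largest falls besides the AHR targets, Tacr1, the receptor for substance P, went from 334 ± 333 to 0.81 ± 0.81 (log2 -7.18 ± 0.68, adjusted p = 0.0031). The kinase gene Stk32b went from 266 ± 46.6 to 1.9 ± 2.06 (log2 -6.80 ± 0.55, adjusted p = 0.0017). Bpifa1, a secreted protein of the airway lining, stood at 34, 269 and 1386 in the WT libraries and at 0.81, 0 and 0 in the Ahr-KO libraries (adjusted p = 0.0096, lost without Ahr-KO library 2 at 0.053). It entered only 3 of the fits that left out 1 library and passed in 2. Cnpy1 stood at 247, 18.1 and 89.5 in WT and was listed at 0 in the 3 Ahr-KO libraries (adjusted p = 0.0068). Cnpy1 likewise entered only 3 such fits and passed in each. Gpr165 was 25.47-fold lower, Mfrp 23.31-fold and Tmem132e 17.74-fold (adjusted p = 0.006, 0.0074 and 0.0031). Ms4a12 was 17.39-fold and the fibrillar collagen gene Col11a1 16.05-fold lower (adjusted p = 0.011 and 0.01). Tacr1 stood at a log2 of -6.40 without WT library 2, Mfrp at -5.13 and Col11a1 at -4.70 without Ahr-KO library 0, Stk32b at -6.18 without Ahr-KO library 1 and Ms4a12 at -4.90 without Ahr-KO library 2.

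Lymphocyte genes were lower in the Ahr-KO lungs. Of 16 tested T cell markers, 11 fell and none rose. They included the co-receptor Cd8a (416 ± 79 against 161 ± 15, 2.54-fold, adjusted p = 0.006), the kinase Lck (2.2-fold, adjusted p = 0.006) and the adhesion receptor Cd2 (2.35-fold, adjusted p = 0.0097). Of 11 markers of NK and cytotoxic cells, 9 fell. Among these were the perforin gene Prf1 (999 ± 191 against 364 ± 97.9, 2.77-fold, adjusted p = 0.0081), the activating receptor Klrk1 (2.9-fold, adjusted p = 0.0091) and the granule protein gene Nkg7 (2.14-fold, adjusted p = 0.0079). Of 13 B cell markers, 8 fell, among them the surface antigen Ms4a1 (3.42-fold, adjusted p = 0.011), the inhibitory receptor Cd22 (2.46-fold, adjusted p = 0.0062) and the IgE receptor Fcer2 (3.09-fold, adjusted p = 0.011). Adjusted over the list alone, 14 T cell, 11 cytotoxic and 12 B cell markers fell. The set test called all 3 lists lower, with camera adjusted p = 3.6e-08 for T cells, 3.6e-08 for cytotoxic cells and 9.9e-08 for B cells. In the same order, these were adjusted p = 0.21, 0.21 and 0.32 with an estimated correlation. The calls of Cd8a, Lck, Cd2, Prf1, Klrk1, Nkg7, Ms4a1, Cd22 and Fcer2 held in each fit that left out 1 library. Gzma (2.33-fold lower, adjusted p = 0.013) lost its call without Ahr-KO libraries 1 or 2 (0.06), and Icos (2.47-fold lower, adjusted p = 0.017) without WT library 0 or Ahr-KO libraries 1 or 2 (0.066). Red blood cell genes had 0 of 9 members past the limma threshold, also adjusted over the list alone (4 at an unadjusted p under 0.05), with a median log2 of -1.11. The lowest p was that of Ahsp, the alpha-haemoglobin chaperone (49.6 ± 10.9 against 27 ± 5.22, adjusted p = 0.091). That list was called lower by camera (adjusted p = 0.029; adjusted p = 0.45 with an estimated correlation). The call was lost after quantile normalisation (adjusted p = 0.059), with equal library totals (0.060) and without WT library 1, WT library 2, Ahr-KO library 0 or Ahr-KO library 1 (highest adjusted p = 0.10). The mean log2 difference of its members was -0.98 (95% interval -2.05 to 0.08).

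Some chemokine and antigen presentation genes fell as well. Of 31 tested cytokines and chemokines, 15 fell and none rose (16 fell adjusted over the list alone). The interferon-induced chemokines Cxcl10 (143 ± 48.3 against 23 ± 2.74, 5.78-fold, adjusted p = 0.0052) and Cxcl9 (4.5-fold, adjusted p = 0.0093) fell, as did the lymphoid chemokine Ccl21 (6513 ± 1805 against 1966 ± 644, 3.33-fold, adjusted p = 0.0096) and the homing chemokine Cxcl12 (1.91-fold, adjusted p = 0.006). In the list of Th17 and type 3 immunity genes, 4 of 8 fell (6 adjusted over the list alone). These were the receptor Ccr6 (3.63-fold, adjusted p = 0.015), its ligand Ccl20 (2.9-fold, adjusted p = 0.048), Il1r1 (1.92-fold, adjusted p = 0.012) and Il6, which is also in the cytokine list and stood at only 5.97 ± 1.03 in WT (adjusted p = 0.028). Of 9 MHC class II genes, 6 fell (8 adjusted over the list alone). Among them were the transactivator Ciita (877 ± 108 against 408 ± 62.3, 2.15-fold, adjusted p = 0.0071), RT1-DOb (2.98-fold, adjusted p = 0.0097), RT1-Da (1.6-fold, adjusted p = 0.016) and the invariant chain gene Cd74 (1.46-fold, adjusted p = 0.022). The RT1 genes are close relatives and their single levels are uncertain where reads were shared. Camera adjusted p was 1.0e-07 for cytokines and chemokines, 0.00067 for type 3 immunity and 3.2e-06 for MHC class II. The same lists gave adjusted p = 0.21, 0.21 and 0.21 with an estimated correlation. Without Ahr-KO library 2, Ccl21 and Il1r1 were not past the threshold (adjusted p = 0.051 and 0.053). RT1-Da (highest adjusted p = 0.069) and Il6 (0.083) lost their calls without Ahr-KO libraries 1 or 2, and Ccr6 (0.069) also without WT library 0. Il6 was below the filter whenever a WT library was left out, so it entered only 3 such fits and passed in 1. Cd74 (0.086) lost it without WT libraries 0 or 1 or Ahr-KO libraries 1 or 2, and Ccl20 (0.14) without any 1 library.

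Macrophage and complement genes moved in the same direction in part. The complement subunits C1qa (1799.7 ± 131 against 489 ± 136, 3.76-fold, adjusted p = 0.0031), C1qb (3.64-fold, adjusted p = 0.0086) and C1qc (3.15-fold, adjusted p = 0.0081), which macrophages make, fell together with the integrin gene Itgax (2.13-fold, adjusted p = 0.034). The other 12 of 16 macrophage and monocyte markers did not pass (7 fell adjusted over the list alone). In the complement list 4 of 14 fell and none rose. These were C1s (2.38-fold, adjusted p = 0.006), C7 (24194 ± 1055 against 9906 ± 3661, 2.55-fold, adjusted p = 0.013), C1r (1.49-fold, adjusted p = 0.015) and the C1 inhibitor Serping1 (1.66-fold, adjusted p = 0.019). In the complement list adjusted over the list alone, 8 fell and 1 rose. Both lists were called lower (camera adjusted p = 0.0028 and 0.00015; adjusted p = 0.44 and 0.38 with an estimated correlation). Mast cell markers were mixed. The high-affinity IgE receptor genes Fcer1a (5.7-fold, adjusted p = 0.015) and Ms4a2 (4.0-fold, adjusted p = 0.038) and the carboxypeptidase Cpa3 (5.15-fold, adjusted p = 0.04) fell. Kit, a receptor tyrosine kinase that lung endothelium also expresses, rose from 1073 ± 249 to 3314 ± 285 (adjusted p = 0.0034). The remaining 5 of 9 did not pass, adjusted over the list alone 2 rose and 4 fell, and the list was not called (camera adjusted p = 0.43). Neutrophil markers and interferon-stimulated genes were not called (camera adjusted p = 0.64 and 0.40), with 1 of 8 and 0 of 20 members past the limma threshold over all genes and over the list alone. Of the 20, 6 were at an unadjusted p under 0.05, and the interferon list was called higher without both libraries numbered 2 (camera adjusted p = 0.025, median log2 0.23). The neutrophil member was Ncf1, a NADPH oxidase subunit gene named after its value was seen (log2 -0.84 ± 0.13, adjusted p = 0.011). The neutrophil list's median log2 was 0.15 with a mean of -0.04, so median and mean differed in sign. Plasma cell markers were not called (camera adjusted p = 0.19). Irf4 (2.31-fold, adjusted p = 0.024) and Pou2af1 (2.02-fold, adjusted p = 0.04) fell and Sdc1, which epithelium also expresses, rose (1.36-fold, adjusted p = 0.03). The other 4 of 7 did not pass, Tnfrsf17 among them (adjusted p = 0.30), and adjusted over the list alone, 1 rose and 2 fell. C1qa, C1qb, C1qc, C1s, Kit and Ncf1 kept their calls when any 1 library was left out. Fcer1a was lost without WT library 0 (0.054). C7, C1r and Serping1 lost their calls without Ahr-KO libraries 1 or 2 (highest adjusted p = 0.055, 0.063 and 0.081), and Irf4 (0.083) also without WT library 0. Pou2af1 (0.13) and Sdc1 (0.10) lost theirs without WT libraries 0 or 1 or Ahr-KO libraries 1 or 2. Itgax (0.13), Ms4a2 (0.13) and Cpa3 (0.15) lost theirs without WT libraries 0 or 2 or Ahr-KO libraries 1 or 2.

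**Figure D2:**
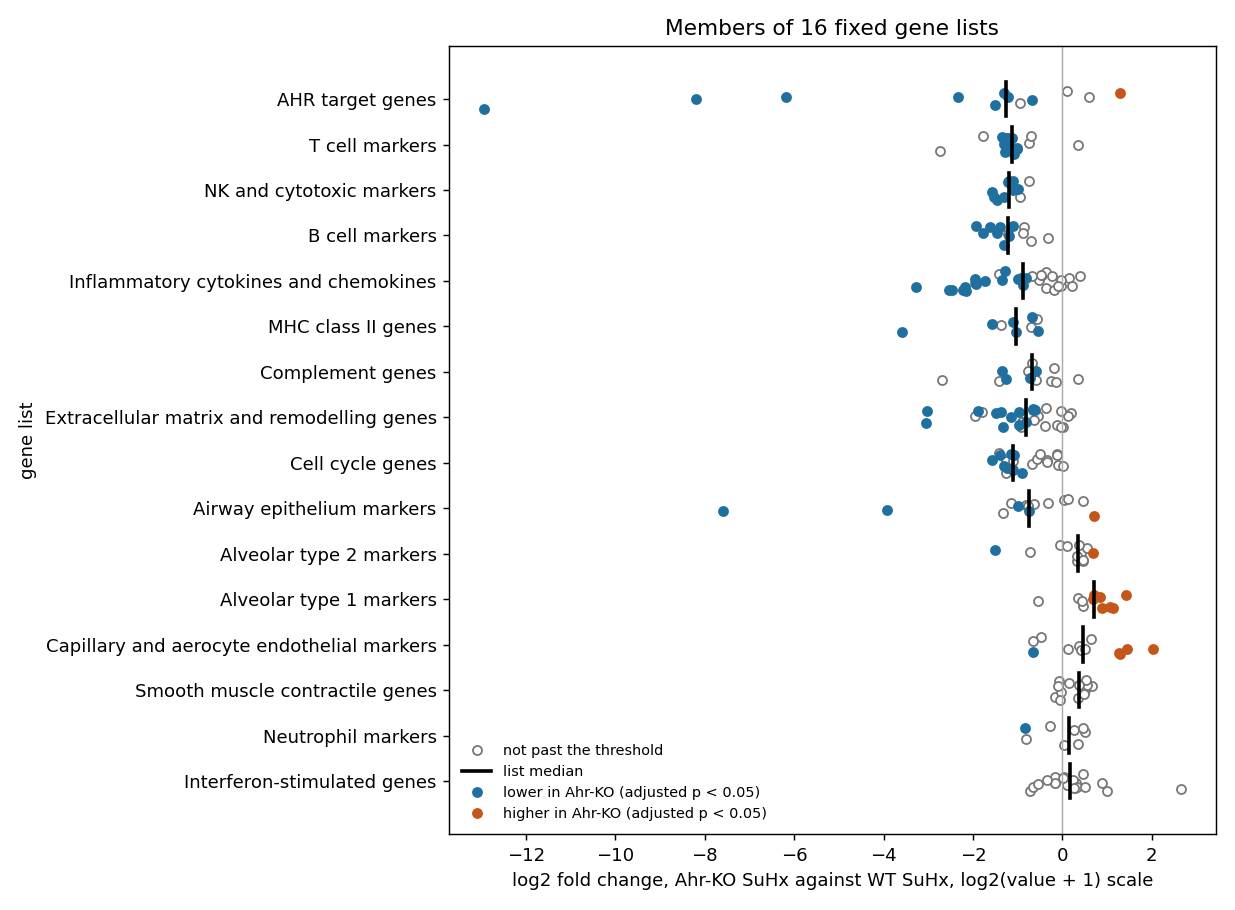
Log2 fold change of each tested member (points) of 16 gene lists, Ahr-KO against WT on the log2(value + 1) scale, with the list median as a vertical bar; filled points passed the threshold (blue lower, orange higher) and open points did not. Lymphocyte, chemokine and matrix lists lie to the left of 0 with medians from -1.21 to -0.81, and alveolar type 1 markers to the right with a median of 0.71.

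Some matrix and proliferation genes fell. Of 27 extracellular matrix and remodelling genes, 13 fell and none rose (18 fell adjusted over the list alone). They included the fibrillar collagen gene Col1a1 (9507 ± 1545 against 3639 ± 379, 2.6-fold, adjusted p = 0.0034), Col14a1 (2.82-fold, adjusted p = 0.0054) and Ltbp2, a protein of elastic fibres (1.75-fold, adjusted p = 0.0078). Of 22 cell cycle genes, 9 fell and none rose (13 fell adjusted over the list alone). Examples were the replication helicase gene Mcm5 (2.96-fold, adjusted p = 0.013), the mitotic kinase Cdk1 (2.47-fold, adjusted p = 0.013), the mitotic motor Kif11 (2.62-fold, adjusted p = 0.019) and the proliferation marker Mki67 (426 ± 42.9 against 233 ± 60.3, 1.86-fold, adjusted p = 0.026). Of 19 immediate early genes, 5 fell (9 adjusted over the list alone). These were Nr4a3 (3.43-fold, adjusted p = 0.011), Egr3 (7.81-fold, adjusted p = 0.016), Egr2 (2.02-fold, adjusted p = 0.02), Atf3 (2.71-fold, adjusted p = 0.021) and, named after its value was seen, Egr1 (log2 -2.57 ± 0.52, adjusted p = 0.021). Of 14 NRF2 target genes, 4 fell and 1 rose (8 fell and 1 rose adjusted over the list alone). The glutathione transferases Gstp1 (2.01-fold, adjusted p = 0.011) and Gstm1 (1.69-fold, adjusted p = 0.02), both with close relatives, the malic enzyme gene Me1 (1.66-fold, adjusted p = 0.024) and, named after its value was seen, the cystine transporter Slc7a11 (log2 -1.54 ± 0.37, adjusted p = 0.037) fell. The glutathione peroxidase Gpx2 rose (1.79-fold, adjusted p = 0.033). Camera adjusted p was 2.3e-08 for matrix genes, 3.7e-07 for cell cycle genes, 5.5e-06 for immediate early genes and 0.0014 for NRF2 targets. With the correlation estimated, it was adjusted p = 0.21, 0.34, 0.32 and 0.21 in that order. Col1a1, Col14a1, Ltbp2, Mcm5 and Nr4a3 kept their calls when any 1 library was left out. Cdk1 and Gstp1 were lost without Ahr-KO library 2 (adjusted p = 0.057 and 0.059) and Egr3 (0.061) also without WT library 0. Kif11 (0.07) and Atf3 (0.069) lost their calls without WT library 0 or Ahr-KO libraries 1 or 2. Egr2 (0.07) lost its call without WT libraries 0 or 1 or Ahr-KO library 1, and Gstm1 (0.081) without WT libraries 0 or 1 or Ahr-KO library 2. Without Ahr-KO libraries 1 or 2 the calls of Mki67 (0.10), Me1 (0.083), Gpx2 (0.13), Slc7a11 (0.12) and Egr1 (0.091) were lost. They were also lost without WT libraries 0 or 1 for Mki67, WT library 0 or Ahr-KO library 0 for Me1, WT libraries 1 or 2 for Gpx2, any 1 WT library for Slc7a11 and Ahr-KO library 0 for Egr1.

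Alveolar type 1 markers went the other way, and some endothelial markers with them. Of 11 alveolar type 1 markers, 7 rose and none fell (9 rose adjusted over the list alone). Among these were the keratin gene Krt7 (4236 ± 774 against 11378 ± 966, 2.71-fold, adjusted p = 0.0031), the homeobox cofactor Hopx (9969 ± 1858 against 20727 ± 1021, 2.1-fold, adjusted p = 0.0071), the kinase anchor Akap5 (2.19-fold, adjusted p = 0.011) and Clic5 (1.79-fold, adjusted p = 0.011). Of 12 capillary and aerocyte endothelial markers, 4 rose. They were Prx, or periaxin (3006 ± 539.8 against 7336 ± 1014, 2.45-fold, adjusted p = 0.0054), the carbonic anhydrase Car4 (2.4-fold, adjusted p = 0.0091), the prostaglandin-degrading enzyme Hpgd (2.71-fold, adjusted p = 0.013) and the lipoprotein lipase anchor Gpihbp1 (4.08-fold, adjusted p = 0.02). Plvap, a protein of endothelial diaphragms named after its value was seen, fell (log2 -0.66 ± 0.17, adjusted p = 0.047). Further, 7 members did not pass, and adjusted over the list alone 7 rose and 1 fell. Of 19 pan-endothelial markers, the angiopoietin receptor Tek (8956 ± 1308 against 16639 ± 2957, 1.85-fold, adjusted p = 0.016) and the junction protein Pecam1 (1.5-fold, adjusted p = 0.044) rose, and Emcn fell (1.28-fold, adjusted p = 0.042). The other 16 did not pass, the nitric oxide synthase Nos3 among them (log2 -0.46, adjusted p = 0.068), and adjusted over the list alone 4 rose and 2 fell. Smooth muscle contractile genes had 0 of 14 members past the limma threshold, over all genes or over the list alone (5 at an unadjusted p under 0.05), with a median log2 of 0.37. Single log2 values were 0.49 for Myl9 (adjusted p = 0.063), 0.66 for Myh11 (adjusted p = 0.085), 0.50 for Lmod1 (adjusted p = 0.089) and 0.54 for Tagln (adjusted p = 0.12). These 4 lists were called higher by camera (adjusted p = 1.9e-06, 0.0033, 0.048 and 0.048). The values were adjusted p = 0.21, 0.42, 0.42 and 0.63 with an estimated correlation. The pan-endothelial call was lost without WT library 0, WT library 2 or Ahr-KO library 1 (highest adjusted p = 0.15) and the smooth muscle call without WT library 1 or Ahr-KO library 2 (highest adjusted p = 0.43), where its median log2 was 0.23 and 0.14. Quantile normalisation ended both (adjusted p = 0.53 and 0.18), as did limma without the trend (0.066 and 0.066) and the fit without both libraries numbered 2 (0.13 and 0.17). The stricter filter on low values ended the smooth muscle call (0.053). Airway markers moved with these groups in the other direction, with a mean log2 difference of -1.21 (95% interval -1.86 to -0.55) in which Bpifa1 (log2 -7.60) and Scgb3a1 (log2 -3.93) weigh most. The median log2 of the airway list was -0.76, at -0.49 without WT library 2 and -0.38 without both libraries numbered 2. Krt7, Hopx, Prx, Car4 and Hpgd kept their calls when any 1 library was left out. Akap5 and Clic5 were lost without Ahr-KO library 2 (adjusted p = 0.055 and 0.0504). Tek (0.059) lost its call without WT library 0 or Ahr-KO library 1 and Gpihbp1 (0.084) without WT library 0 or Ahr-KO libraries 1 or 2. Pecam1 (0.14) lost it without any 1 library other than WT library 1, and Emcn (0.14) and Plvap (0.14) without any 1 other than WT library 2.

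Of 14 airway epithelium markers, 4 fell. These were Bpifa1, the secretoglobin Scgb3a1 (422 ± 188 against 30.7 ± 20.5, 15.23-fold, adjusted p = 0.012), the ciliary dynein Dnah11 (1.98-fold, adjusted p = 0.013) and, named after its value was seen, Foxj1, a regulator of ciliated cells (log2 -0.74 ± 0.16, adjusted p = 0.03). Tppp3, another marker of ciliated cells, rose (1.64-fold, adjusted p = 0.025), 9 did not pass, and adjusted over the list alone 6 fell and 1 rose. The list was called lower (camera adjusted p = 0.0099; adjusted p = 0.42 with an estimated correlation; camera adjusted p = 0.071 without WT library 2 and 0.14 without both libraries numbered 2). Alveolar type 2 markers were not called (camera adjusted p = 0.055; 0.020 to 0.045 in the 5 alternatives that called it, the fit without Ahr-KO library 1 among them). The transcription factor Etv5 rose (1.62-fold, adjusted p = 0.019) and the chitinase Chia fell (7530.4 ± 2666 against 2598 ± 574, adjusted p = 0.013). The surfactant gene Sftpb stood at 76584 ± 5397 against 112213 ± 8256 (adjusted p = 0.054) and Lcn2 at 5731 ± 1364 against 3456 ± 571 (adjusted p = 0.053). Adjusted over the list alone, 5 of the 12 type 2 markers rose and 2 fell. Scgb3a1 kept its call when any 1 library was left out, with a log2 of -3.93 in all 6 libraries and -3.19 without Ahr-KO library 2. Dnah11 and Chia were lost without Ahr-KO library 2 (adjusted p = 0.053 and 0.065), and Etv5 (0.079) also without WT library 0. Tppp3 (0.088) lost its call without WT library 1 or Ahr-KO libraries 1 or 2, and Foxj1 (0.094) without WT libraries 0 or 1 or Ahr-KO libraries 0 or 2.

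Genes of the pathways tied to pulmonary hypertension changed singly. In the BMP and TGF-beta list of 25 genes, the growth factor Tgfb1 (1438 ± 206 against 706 ± 7.37, 2.02-fold, adjusted p = 0.0051), the BMP antagonist Grem1 (5.84-fold, adjusted p = 0.012) and the inhibin subunit Inhbb (1.51-fold, adjusted p = 0.018) fell. The BMP receptor Bmpr2 (3597 ± 1207 against 6286 ± 263, 1.81-fold, adjusted p = 0.036) and its target Id3 (1.6-fold, adjusted p = 0.03) rose. The counts were alike adjusted over the list alone, with 2 higher and 3 lower, and the list was not called (camera adjusted p = 0.44). In the list of 26 vasoactive and pulmonary hypertension genes, Tph1, the enzyme that starts serotonin synthesis outside the brain, fell (29.2 ± 9.06 against 3.71 ± 1.92, 6.61-fold, adjusted p = 0.013). Bmpr2, the vasoactive intestinal peptide receptor Vipr1 (1.36-fold, adjusted p = 0.037) and the angiotensin-converting enzyme Ace (20015 ± 2177 against 28675 ± 3267, 1.43-fold, adjusted p = 0.044) rose. In the vasoactive list, 5 rose and 2 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.94). Fibroblast and pericyte markers were just outside the threshold as a list (camera adjusted p = 0.055; 0.024 to 0.043 in the 5 alternatives that called it, the fits without WT library 2, Ahr-KO library 0 or Ahr-KO library 2 among them). Over all genes, and adjusted over the list alone, 2 of 14 fell, Rgs5 (2.41-fold, adjusted p = 0.016) and Pi16 (2.41-fold, adjusted p = 0.02). Members that did not pass had log2 values of 0.40 for Cspg4 (adjusted p = 0.076) and -0.48 for Meox2 (adjusted p = 0.13). Of 22 hypoxia targets, the glucose transporter Slc2a1 (1.32-fold, adjusted p = 0.03) and the glycolytic enzyme Pgk1 (1.23-fold, adjusted p = 0.046) fell. The other 20 did not pass, with log2 values of 0.47 for P4ha1 (adjusted p = 0.063) and -0.69 for Bhlhe40 (adjusted p = 0.069). Among hypoxia targets adjusted over the list alone, 2 rose and 5 fell, and the list was not called (camera adjusted p = 0.14). Tgfb1 and Tph1 kept their calls when any 1 library was left out. Grem1 was lost without Ahr-KO library 2 (0.059) and Inhbb (0.075) also without WT library 1. Id3 (0.11) and Pi16 (0.068) lost their calls without WT library 0 or Ahr-KO libraries 1 or 2. Rgs5 (0.07) lost its call without WT library 1 or Ahr-KO libraries 1 or 2, and Slc2a1 (0.11) without WT libraries 0 or 1 or Ahr-KO libraries 1 or 2. Bmpr2 (0.13), Vipr1 (0.11), Ace (0.13) and Pgk1 (0.15) were each past the threshold in only 1 of the 6 fits that left out a library, the one without WT library 2.

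**Figure D3:**
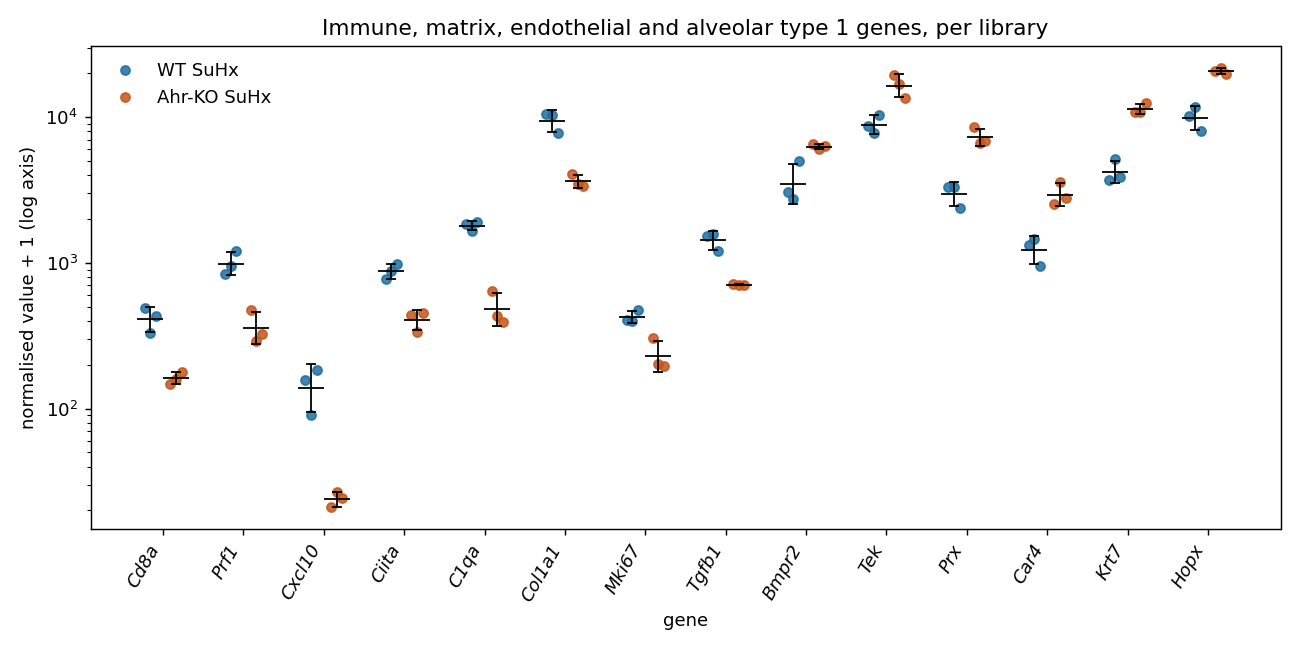
Normalised value + 1 on a log axis for immune, matrix, proliferation, pathway, endothelial and alveolar type 1 genes, 1 point per library (blue WT SuHx, orange Ahr-KO SuHx), with the mean and SD of the log2 values as bars. For each gene drawn the 3 Ahr-KO points lie on one side of the 3 WT points, lower from Cd8a to Tgfb1 and higher from Bmpr2 to Hopx.

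The remaining lists were not called. Leaving out libraries brought camera calls for clock genes, higher in Ahr-KO (adjusted p = 0.014 without WT library 2 and 0.0038 without both libraries numbered 2), cardiac muscle genes (0.017 without WT library 0, with a median log2 of -1.95, and 0.0079 in the opposite direction without both libraries numbered 2, with a median log2 of 1.26), lipid synthesis genes, lower (0.015 without WT library 1) and mesothelial markers, lower (0.036 without WT library 2, 0.017 without Ahr-KO library 2 and 0.0014 without both libraries numbered 2). The adipocyte list was called lower with no filter on low values (0.044) and the lipid synthesis list after quantile normalisation (0.032). Clock genes had 0 of 16 members past the limma threshold, over all genes or over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.18). Within the WT group, library 2 stood apart in them. The clock output gene Dbp stood at 2357 in it against 112 and 133 in WT libraries 0 and 1. The clock activator Arntl stood at 203 against 1046 and 897. In Ahr-KO libraries 0, 1 and 2, Dbp stood at 394, 422 and 1559 and Arntl at 857, 1036 and 462. WT library 2 also stood apart on the second principal component (19.3% of the variance). Without both libraries numbered 2, a setting added after the data were seen, 553 genes were past the threshold, 268 higher and 285 lower, and 439 of them were among the 1655 with the same direction. Cardiac muscle genes had 0 of 12 members past the threshold, over all genes or over the list alone, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.42). They varied between libraries in both groups, with the atrial myosin gene Myh6 at 29, 569 and 1985 in the WT libraries and at 775, 474 and 0 in the Ahr-KO libraries. Skeletal muscle (camera adjusted p = 0.23), adipocyte (0.23), lipid and cholesterol synthesis (0.20) and mesothelial lists (0.18) each had 1 member past the threshold, named after its value was seen. These were the myosin gene Myh1 (log2 -3.63 ± 0.46), the gluconeogenic enzyme gene Pck1 (log2 -2.80 ± 0.50), the desaturase gene Scd (log2 -0.95 ± 0.14) and the keratin gene Krt19 (log2 0.95 ± 0.12). Adjusted over the list alone, the counts were 1 lower, 1 lower, 1 lower, and 1 higher with 3 lower. Pck1 was lost without WT libraries 0 or 1 or Ahr-KO library 2 (0.06) and Scd without Ahr-KO library 2 (0.0503). Myh1 entered only 3 of the fits that left out 1 library and passed in each. Oxidative phosphorylation genes had 0 of 16 members past the threshold, over all genes or over the list alone, 1 at an unadjusted p under 0.05, and a median log2 of 0.0011 against a mean of -0.02, which differ in sign, with camera adjusted p = 0.86. Of the Y-linked genes used as a check of the libraries, Kdm5d lay between 1128 and 1529 and Eif2s3y between 862 and 1256 in all 6 libraries, and Ddx3y stood at 4.09 or less in each.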

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

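The tests of limma-voom, equal library totals and the fit without both libraries numbered 2 were chosen after the result was seen. No called gene among the 113 named ones and none of the 19 called lists changed direction under any alternative run. The number of changed genes stayed within 1.5 times of 1655 with quantile normalisation (1354), robust limma (1660), no filter (1491), a stricter filter (1683), a pseudocount of 0.1 (1576), limma-voom (1622) and equal library totals (1762), and 13, 1, 4, 0, 3, 9 and 4 of the 113 named genes lost their calls in these fits. Without the trend there were 952 changed genes, 301 of them higher, 33 of the 113 named genes lost their calls, and the cause was not tested. An adjusted p under 0.10 gave 2853 (1286 higher, 1567 lower) and a fold of at least 2 gave 676 (135 higher, 541 lower), as these settings move the threshold itself. Equal library totals left 448 higher genes, since the Ahr-KO totals were larger. Leaving out 1 library gave 407 to 1834 changed genes (135 to 930 higher, 272 to 920 lower) with fewer samples, and 6 to 59 of the named genes lost their calls in 1 such fit, and 51 of the 113 named genes were past the threshold in every such fit they entered. Without both libraries numbered 2 there were 553 (268 higher, 285 lower), and 66 of the 107 called named genes that entered lost their calls. The number of lists called was 18 to 21 in the fits with the preset correlation, 13 with fry and 0 with an estimated correlation, for which the allowance for correlated members is the change made.

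The library numbers are not said to pair the samples. Same-numbered libraries had correlations of -0.20, 0.08 and -0.14 in their deviations from the group means over 12640 genes. Not every library correlated best with its own number. Such correlations within groups of 3 do not exclude a batch shared by number. Both libraries numbered 2 were the shallowest of their group, with the highest Dbp (2357 in WT, 1559 in Ahr-KO) and the lowest Arntl (203 and 462). With the number as a replicate block, 899 genes were past the threshold (334 higher, 565 lower), 859 of them shared with the fit without it in the same direction, 17 named genes lost their calls, and the clock list gained one (camera adjusted p = 0.030).

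Changes of sign occurred only in results that were not past the threshold with all 6 libraries, and the cause was not tested. Ahr was at -0.012 with quantile normalisation and with equal totals, and ranged from -0.061 to 0.29 when 1 library was left out. The oxidative phosphorylation median was -0.064 with quantile normalisation, -0.090 with equal totals, -0.030 without both libraries numbered 2, and -0.017 to 0.013 with 1 library left out. The neutrophil median was -0.013 with no filter and -0.29 to 0.35 with 1 library left out. Leaving out 1 library gave ranges of -0.24 to 0.92 for Ddx3y, -0.16 to 0.41 for Nedd9, -1.95 to 0.51 for the cardiac median, -0.53 to 0.060 for skeletal muscle and -0.23 to 0.053 for lipid synthesis. Without both libraries numbered 2, Ddx3y was at -0.42, the cardiac median at 1.26 (past the threshold there, adjusted p = 0.0079) and the adipocyte median at 0.031. Depth limits genes whose values lie near 1 read, such as Cyp1a2 and Ddx3y.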

Other observations

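The tests of the 5 added gene lists, of blood, lymph node, dilution, lung periphery and sequencing depth, and of the genes beside Ahr were chosen after the result was seen. Basement membrane genes went both ways. Of 22 tested, 9 rose and 4 fell. The laminin chain Lama3 rose from 1927, 2373 and 2221 in WT libraries 0, 1 and 2 to 4155, 4553 and 5317 in the Ahr-KO libraries (log2 1.10 ± 0.12, limma adjusted p = 0.0042), the collagen IV chain Col4a3 rose (log2 1.62 ± 0.21, adjusted p = 0.006), as did perlecan, Hspg2 (log2 0.91 ± 0.11), and Lama5 (log2 1.09 ± 0.15). Col18a1 fell (log2 -1.22 ± 0.14, adjusted p = 0.0043), and Lama1 stood at 11, 10.7 and 14 in WT and was listed at 0 in the 3 Ahr-KO libraries. Lama1 entered only 3 of the fits that left out 1 library and passed in each. The list gave camera adjusted p = 0.0056, with adjusted p = 0.22 with an estimated correlation and 0.26 by fry. Among fibulins, small proteoglycans and matricellular genes, 5 of 14 fell and 1 rose: the thrombospondin Thbs2 fell from 479.8, 501 and 522 to 79, 64.5 and 53.2 (adjusted p = 0.00051), biglycan, Bgn, fell from 17435, 15981 and 17024 to 7966, 6911 and 8178 (adjusted p = 0.0025), Fbln1 (log2 -1.25 ± 0.18), Fbln5 (log2 -0.70 ± 0.10) and Fbln2 (log2 -0.94 ± 0.15) fell, and Thbs3 rose (log2 1.10 ± 0.20). Camera gave adjusted p = 0.00097 for it (0.098 as adjusted p with an estimated correlation, 0.00019 by fry). Fbln2 lost its call without Ahr-KO library 2 (0.057) and Thbs3 without Ahr-KO libraries 1 or 2 (0.054).

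Flavin monooxygenases rose beside Fmo1: Fmo2 stood at 7402, 4300.0 and 6516 in WT and 22468, 12173 and 14015 in Ahr-KO (log2 1.40 ± 0.27, adjusted p = 0.018) and Fmo4 rose (log2 0.81 ± 0.18, adjusted p = 0.029), while 2 of 5 did not pass (camera adjusted p = 0.0052, adjusted p = 0.11 with an estimated correlation, 0.0070 by fry). Of 16 axonemal dynein genes, which build the motors of cilia, 5 fell, Dnah11, Dnah6 (log2 -1.11 ± 0.21), Dnai2 (log2 -1.45 ± 0.30), Dnah7 (log2 -0.97 ± 0.22) and Dnali1 (log2 -0.69 ± 0.17); camera adjusted p was 0.00097, with adjusted p = 0.24 with an estimated correlation and 0.089 by fry. Of 10 genes of the actin-branching Arp2/3 complex, 3 fell, Actr3 (log2 -0.52 ± 0.08), Arpc4 (log2 -0.54 ± 0.09) and Arpc1b (log2 -0.51 ± 0.10), with camera adjusted p = 0.0011, adjusted p = 0.18 with an estimated correlation and 0.0078 by fry. These 5 lists were written after their members had been seen, so their tests do not decide whether the groups move together. Leaving out 1 library ended the calls of Fmo2 and Arpc4 (without Ahr-KO library 2, 0.069 and 0.057), Dnah6 and Actr3 (without Ahr-KO libraries 1 or 2, highest adjusted p 0.082 and 0.055), Dnai2 (without WT library 1 or Ahr-KO libraries 0 or 2, 0.094), Arpc1b (without WT libraries 0 or 1 or Ahr-KO libraries 1 or 2, 0.091), Fmo4 (without any 1 library other than WT library 2, 0.12), and Dnah7 and Dnali1 (without any 1 other than Ahr-KO library 1, 0.12 and 0.13).

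The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1655 changed genes (692 higher, 963 lower), and the highest other split gave 1 (1 higher, 0 lower). It gave 19 called lists, and the highest other split also gave 19, so that 3 of the 10 splits, the real one included, reached that number. The lowest other split gave 3. Camera with the preset correlation thus called lists in every split that mixes the genotypes. Its list calls therefore do not by themselves show a genotype difference.

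Lymphocyte markers were lower in Ahr-KO. Less residual blood in the Ahr-KO lungs would lower neutrophil markers too, but the T cell minus neutrophil score fell by 1.12 on the log2 scale (95% interval -1.62 to -0.62), and the neutrophil score differed by -0.04 (-0.80 to 0.72), with S100a9 at 555 ± 253 in WT and 575 ± 261 in Ahr-KO. The red blood cell score did go with it, at -0.98 (-2.05 to 0.08), with Hbb at 11198 ± 5790 against 4925 ± 2058. Pieces of lymph node taken by chance in some WT samples would spread the WT samples. The gap between the groups in the T and B cell score was instead 1.30 times the largest range within a group (0.73 against 0.56 log2). This score and the T cell minus neutrophil score use markers already seen to fall, so their direction was known beforehand. The gap does not exclude node tissue in every WT sample. Because the red blood cell score went the same way and the neutrophil interval is wide, less blood as a part of the difference stays open. A difference in dissection between the groups as a whole and a difference by genotype also stay open, untested.

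Alveolar type 1 markers were higher in Ahr-KO. A loss of other cells could raise all alveolar markers alike, but the type 1 minus type 2 score was higher by 0.56 (0.21 to 0.90). The type 2 list had a mean log2 of 0.12 but a median of 0.35, with 9 of 12 members above 0. Type 1 markers had a median of 0.71. Falling members such as Chia (log2 -1.50) lower the type 2 mean, so the score does not settle whether there was such dilution. More peripheral pieces of lung could raise type 1 and lower airway markers (mean log2 difference -1.21, -1.86 to -0.55, median -0.76, and median -0.49 without WT library 2). Smooth muscle, which would then be lower too, differed by 0.26 (-0.22 to 0.75), an interval that includes 0, so this stays open, as does a genotype effect.

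Within the WT group, clock genes set library 2 apart. Its lower depth would move genes of like abundance alike, but the 14 members of the clock list other than Dbp and Arntl differed by more. Dbp and Arntl had drawn attention to the library. The mean difference of the 14 from the other WT libraries was 1.38 on the log2 scale in either direction (7 higher and 2 lower by at least 1). The highest of 10000 random lists of like abundance reached 0.78 (median 0.28). The share of 1e-04 is therefore the smallest that they can give. A different time of day at tissue collection may explain it: of 4 further clock output genes, 3 were higher in that library than in both other WT libraries, namely Usp2 (147 against 108 and 105), Wee1 (607 against 352 and 335) and Tspan4 (18.2 against 11.0 and 18.1, a margin of under 1 read), and Lonrf3 was not. In Ahr-KO library 2, where Dbp was also highest (1559), 0 of the 4 were. Several core clock genes nevertheless moved there as in WT library 2. Against the other Ahr-KO libraries, log2 differences were 0.99 for Per2, 0.97 for Per3, 0.94 for Nr1d1 and -1.03 for Arntl. Clock went the other way (-0.33, against 0.04 in WT library 2). The 4 further genes therefore do not decide on the time of day. In several clock genes WT libraries 0 and 1 lay below all Ahr-KO libraries, while WT library 2 did not. Nr1d1 stood at 309, 865 and 3860 in WT libraries 0, 1 and 2 and at 1965, 2932 and 4619 in Ahr-KO. Tef stood at 2068, 2408 and 6404 against 4874, 4488 and 5829. For Arntl, Npas2 and Ciart the Ahr-KO libraries overlapped with WT libraries 0 and 1. A difference in collection time between the groups was not tested and stays open. Collection times are not given in the sources used here, and no biological explanation was tested.

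Among the 25 tested genes on each side of Ahr in GRCr8 gene order, 4 of 50 were past the threshold, G2e3 (log2 1.48 ± 0.21), Lrrn3 (log2 -0.90 ± 0.19), Pik3cg (log2 -0.91 ± 0.17) and Scin (log2 -1.51 ± 0.33), against 1571 of 14368 other genes (8% against 10.9%, 1-sided Fisher exact p = 0.81). Lrrn3 lost its call without any 1 library other than WT library 2 (highest adjusted p = 0.098), Pik3cg without Ahr-KO libraries 1 or 2 (0.072), and Scin without WT library 1 or Ahr-KO libraries 1 or 2 (0.10).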
